A study of Homo sapiens with 21 samples.

How the data were processed

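The series holds 21 Drop-seq libraries of K562 cells, a human erythroleukaemia line, that carry dCas9-KRAB, a Cas9 without cutting activity joined to a repressor domain. Drop-seq captures single cells in droplets with barcoded beads. Per the labels, each library mixes cells given TNF-alpha for 1 h, which carry the barcode of sgRNA64, with mock-treated cells, which carry that of sgRNA63, combined in one tube shortly before the run. Both guides are listed as targeting an enhancer of HSBP1, which served as the control target. The labels name 2 bioreps, with 16 and 5 libraries, and 6 of the biorep1 libraries carry an extra description (JD130). The labels give no separate cultures within a biorep, so the libraries of a biorep may share one treated and one mock culture. The p-values therefore measure the spread between libraries, which may be partly technical. Treatment and culture are confounded within a biorep. Treatment and guide are confounded in all 21 libraries, so the bioreps cannot tell TNF from a difference between the 2 guides.

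The deposited tables of single libraries hold raw counts per RefSeq transcript and cell barcode, with no normalization by the authors. Per the submitters' processing notes, reads were processed with Picard and featureCounts 1.5.0 against hg19; the aligner is not given in the sources used here. The strand setting of the counting is not given either, so values of overlapping or antisense genes are uncertain, and so are those of the near-identical pairs HBG1 and HBG2, HBA1 and HBA2, and HSPA1A and HSPA1B. The deposited barcode tables list, for each cell barcode, the sgRNA barcodes seen with it and the reads of each; a further deposited list ties the barcode number of each of the 2 guides to its treatment. Per the file headers, 51096 transcripts and the guide vector were counted. A read over several transcripts was counted for each: of 6734 genes with several transcripts and 100 or more counts, 35.2% had every transcript within 1% of the highest. A gene's value was therefore its transcript with the highest total, which gave 26538 gene symbols, of which 21121 had a count. The vector took 0.195% of the counts and was left out. No feature lay on the mitochondrial chromosome, so the planned list of mitochondrially encoded genes and the percent of mitochondrial counts were not computed, and 19 of the 20 fixed gene lists were tested. LTB, TNF and IER3 have further copies on alternative MHC haplotype sequences in the tables.

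A count in a rarely seen gene (in fewer than 6% of a library's barcodes) came with 2.11 to 8.51 counts per barcode on average, by library. The counts thus behave as reads, not as molecules collapsed by identifier, and intervals and floors below cover counting error only. Totals over all barcodes of a library ranged from 2653243 (biorep1 batch 5) to 13450793 (biorep1 batch 8).

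Of 1943 cell barcodes, 614 had the TNF barcode alone, 807 the mock barcode alone, 218 both and 304 neither. The 1421 barcodes with one treatment barcode were used. The 218 barcodes with both treatments were left out as doublets; doublets of the same treatment stay in, since no other doublet caller was run. The deposited series-wide matrix of raw counts has 880 columns, of which 765 have a barcode found in a library table. Of these, 764 equal the library table in every value, all from JD130 libraries, so this matrix served as an alternative choice of cells for those 6 libraries. It left out 83 JD130 cells with one treatment barcode, of which 80 had 1 sgRNA read, and held 0 cells with 1 read. Results from it thus rest on a subset of the JD130 cells and largely repeat those of the JD130 libraries alone. The other 115 columns of the series-wide matrix name no library and were not used here. The reference annotation at hand is of another genome build, so coordinates are those in the files.

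The comparisons, tests, gene lists and alternatives were fixed before the data were examined, except where a test or alternative is named as chosen later. In each library, the counts of its TNF cells and of its mock cells were summed separately, giving 42 sums; every library had 10 or more cells of each treatment. Genes with 100 or more counts over all sums were tested with edgeR 4.0.16 in R 4.3.3 (TMM factors, glmQLFit with legacy = FALSE, glmQLFTest), with the library as the block of each pair. CPM are counts scaled to a common library size with these factors. The threshold was a Benjamini-Hochberg adjusted p of 0.05. A term for treatment by biorep, and within biorep1 for treatment by JD130 description, tested differences of the effect. Gene lists were tested with limma 3.58.1 (voom with the same pairs, then camera with a preset correlation of 0.01), with an estimated correlation and with fry as alternatives. Camera compares a list with all other tested genes.

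The tests were run on simulated data: negative binomial counts with each gene's mean set by its share of a library and its dispersion by the fit, with chosen genes then raised or lowered in the TNF sums. With 200 changed genes, of 11973 tested, the edgeR test named above made 142 calls, of which 60 were false (42.3%), and recovered 60.8% of genes changed by a log2 of 1. With a trended dispersion (legacy = TRUE), edgeR made 59 calls, 0 of them false, and recovered 41.2%. DESeq2 1.42.0 made 86 calls with 15 false (17.4%), and limma voom 66 calls with 3 false (4.55%). With 680 changed genes, of 11948 tested, the share of false calls was 22.8% with the edgeR test and 3.15% with the trended dispersion. The fixed test was kept, and the trended dispersion was added as an alternative after this result was seen. For biorep2 alone, with 9181 genes tested, 11.8% of genes changed by a log2 of 1 were recovered.

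Single cells were compared after drawing each cell down to 16100 counts, the 25th percentile of totals rounded down; 126 TNF and 228 mock cells were shallower and were left out. For 13 fixed genes, the share of cells with a count was taken per library and treatment. The NF-kB list score is the percent of a cell's thinned counts in the NF-kB list. Differences between TNF and mock cells over libraries had two-sided sign-flip permutation tests with 100000 resamples, and exact ones where fewer than 10 libraries entered (numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6, matplotlib 3.10.9, Python 3.11.15). Intervals for differences of 2 percentages are Newcombe's, at the 95% level.

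The genes named in the text follow a fixed rule. Of genes past the threshold with the same sign in both bioreps fitted alone, these are the 15 largest rises and the 10 largest falls. From each list came the 2 to 4 members with the lowest p past the threshold, or the 2 with the highest mean count where none passed. The 13 genes of the shares of cells and the 5 lowest p of an interaction complete the rule; genes outside it are named as chosen after their values were seen. Not every gene the rule names is described: some enter only the counts of named genes, 4 are not reported here, and no other gene took their place.

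The alternatives fixed in advance were DESeq2 size factors in the edgeR fit, no factors, a DESeq2 Wald test, no filter beyond 1 count, filterByExpr, a minimum of 500 counts, no replicate block, sums per biorep, sums per set of libraries (JD130, other biorep1, biorep2), either biorep alone and each library left out in turn. They also held the series-wide matrix, no ribosomal protein genes, no thinning, all cells of a biorep together, the top 5% of cells by counts left out, and limma on log2 of mean CPM per cell plus 1. A minimum of 1000 counts per cell was planned and removed no cell, as the lowest total was 2958. Chosen after seeing the data were cells with 2 or more sgRNA reads, cells with 2000 or more genes, JD130 libraries alone, the other biorep1 libraries alone, sums over transcripts, limma voom for single genes, the trended dispersion and a robust quasi-likelihood fit. Libraries with too few cells of a treatment dropped out of an alternative: 19 of 21 libraries stayed without the top 5% of cells and 20 with 2 or more sgRNA reads, so values there reflect fewer libraries as well as fewer cells.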

Results

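Messenger RNA was counted in single K562 cells by Drop-seq in 21 libraries, 16 of biorep1 and 5 of biorep2. Each library held both treatments, and a cell was assigned to TNF-alpha or mock by the guide barcode seen with it, which gave 614 TNF and 807 mock cells. The counts summed per library and treatment ranged from 719309 (biorep2 batch 4, mock) to 5340525 (biorep1 batch 8, TNF). The median counts per cell were 36821 in TNF and 27740 in mock cells, with 4005 and 3518 genes detected.

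The comparison of TNF with mock cells addressed which genes respond within 1 h of TNF-alpha, a cytokine that activates the transcription factor NF-kB. After TNF, K562 cells had far more RNA of inhibitors and targets of NF-kB. ICAM1, an adhesion molecule of the cell surface (chromosome 19, 10381517 to 10397291, plus strand, hg19), stood at 423 ± 99.6 CPM (normalised counts per library and treatment; SD, n = 21 libraries) against 34.7 ± 14.6 in mock cells, a log2 change of 3.68 ± 0.11 (SE; adjusted p = 5.86e-23; higher in 21 of 21 libraries). NFKBIA, the inhibitor that NF-kB itself induces (chromosome 14, 35870716 to 35873960, minus strand), stood at 801 ± 194 against 91.5 ± 52.1 CPM, a log2 change of 3.20 ± 0.11 (adjusted p = 3.42e-21; 21 of 21). IER3, an early response gene that modulates cell death, rose from 45.4 to 773 CPM. The chemokines CXCL8, CXCL3, CXCL1 and CXCL2, which attract neutrophils, rose by log2 values of 4.63 ± 0.45, 4.21 ± 0.21, 3.84 ± 0.66 and 3.56 ± 0.64, and the cytokine genes LTB and TNF by 4.29 ± 0.22 and 4.28 ± 0.54. BIRC3, which restrains cell death (4.12 ± 0.33), CD83, a surface protein of activated immune cells (4.00 ± 0.20), TNFRSF9, a costimulatory receptor (3.58 ± 0.35), BTG2, a brake on proliferation (3.24 ± 0.21), and SDC4, a cell surface proteoglycan (3.21 ± 0.20), completed the large rises, with C10orf10.

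Among changed genes with the same sign in both bioreps fitted alone, C10orf10 had the largest fitted rise. It had only 3 mock counts against 263 in TNF cells: the ratio of counts per total was 95.1, with a 95% exact interval for counting error of 32.2 to 464. With DESeq2 it did not pass (log2 change 4.00, adjusted p = 0.179). The fold of C10orf10, CXCL8, TNF, CXCL1, TNFRSF9 and CXCL2 moved by over 1.5 times without a single library. Without biorep1 batch 11 the log2 change of C10orf10 was 6.60, without biorep2 batch 5 that of CXCL8 was 5.25, without biorep1 batch 9 those of TNF and CXCL2 were 5.35 and 5.83, without biorep1 batch 6 that of CXCL1 was 5.98, and without biorep2 batch 3 that of TNFRSF9 was 4.19. In the biorep1 libraries outside JD130, CXCL1 and CXCL2 did not pass (2.82, adjusted p = 0.101, and 1.44, adjusted p = 0.348), nor did CXCL1 with sums per biorep (0.0522) or CXCL2 with sums per set of libraries (0.0557).

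Fewer genes fell by as much. PHGDH, which starts serine synthesis, fell by 2.03 on the log2 scale (SE 0.28; 16.8 against 61.1 CPM; lower in 18 of 21 libraries), and CTH, which makes cysteine, by 1.98 (SE 0.24; 23.8 against 84.9 CPM; 18 of 21). In biorep1 these were -2.29 and -2.33, and in biorep2 -0.75 and -0.19. STC2, a secreted glycoprotein, fell by 1.55 and the pseudogene NUDT16P1 by 1.71. The other 6 of the 10 largest falls passed in the planned test but not with a trended dispersion: SPATA22 (log2 change -2.47), BORCS6 (-2.07), LINC00526 (-1.84), CD99L2 (-1.81), PCCA (-1.61) and PTPN6 (-1.55) had adjusted p of 0.0571 to 0.404 there. BORCS6 and CD99L2 also missed the threshold with DESeq2 (0.0748 and 0.109), and CD99L2 with limma voom (0.111). With cells of 2000 or more genes, the fall of SPATA22 was nearly gone (-0.19, adjusted p = 0.749), and CD99L2 missed as well (-1.26, 0.0674). NUDT16P1 did not pass in the JD130 libraries alone (-0.74, adjusted p = 0.374), in the series-wide matrix (-0.85, 0.334) or without the top 5% of cells by counts, which also left only 19 libraries (-0.90, 0.385). PTPN6 and BORCS6 also missed without the top 5% of cells (0.0915 and 0.0998) and in the biorep1 libraries outside JD130 (0.109 and 0.0869), STC2 in the latter (-1.34, 0.0668), and PTPN6 in the JD130 libraries alone (-0.89, 0.292).

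Of 12150 genes tested, 1318 changed (edgeR quasi-likelihood, library as block, adjusted p under 0.05): 729 were higher and 589 lower after TNF, so that 55.3% of the changed genes were higher. This balance moved with the scaling: without normalization factors, 1281 genes changed and 40.3% were higher. On simulated data with 680 changed of 11948 genes, 22.8% of this test's calls were false, and 42.3% with 200 changed of 11973 genes. With a trended dispersion, for which the simulated share was 3.15%, 682 genes changed (455 higher, 227 lower), of which 668 were among the 1318. In the planned test, 891 of the changed genes had the same sign in both bioreps fitted alone (528 higher, 363 lower), and 790 were also called with each library left out in turn. With sums per biorep, the unit that fits a possibly shared culture, 36 genes changed, and with sums per set of libraries 84. The 15 largest rises passed with both dispersions.

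**Figure D1:**
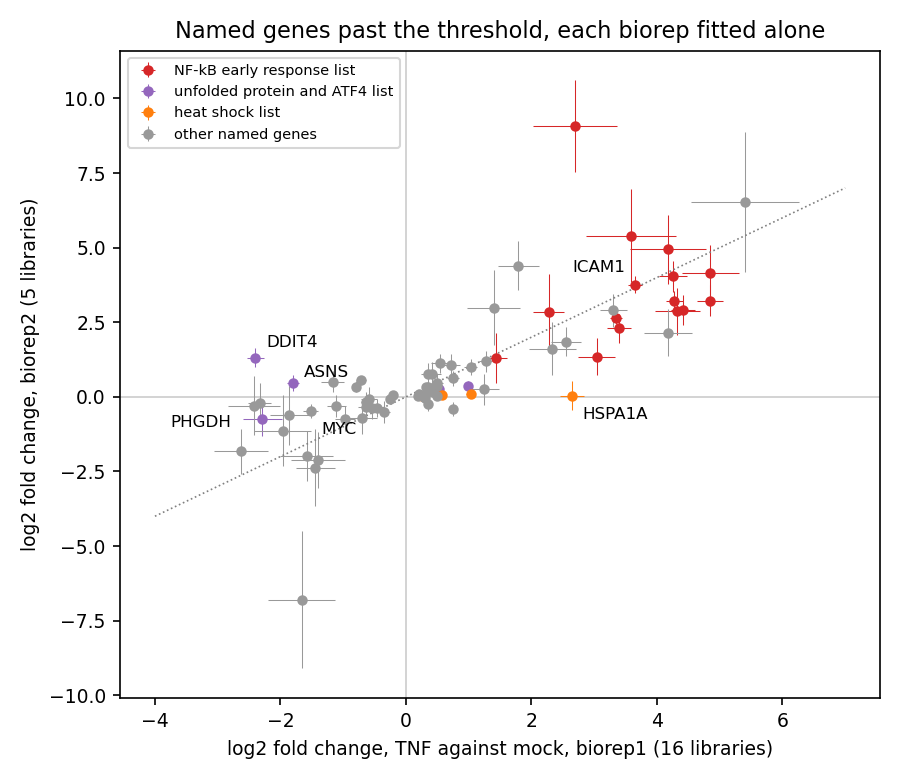
Log2 fold change (TNF against mock) in biorep1 on the horizontal axis and in biorep2 on the vertical axis, each fitted alone, for 77 named genes past the threshold over all libraries; each point is a gene with SE bars, coloured by list (NF-kB, ATF4, heat shock, other), and the dotted line marks equal values. Of these, 67 lie on the same side of 0 in both bioreps. Part of this is built in, because the largest rises and largest falls were picked for the same sign in both bioreps. All drawn genes also passed a fit that holds both bioreps, so the 67 are no independent measure of agreement. ASNS, DDIT4 and MTHFD2 lie below 0 in biorep1 and above it in biorep2. The biorep2 values of C10orf10, CXCL2 and BORCS6, with 0 counts in one treatment there, depend on the prior count.

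NF-kB early response genes, fixed as a list in advance, rose together: of 33 measured, 27 were higher and 0 lower (29 and 0 adjusted over the list alone; 27 and 0 with a trended dispersion), with a median log2 change of 2.88. The list differed from the other genes with an adjusted p of 8.13e-55 (camera). Its member IL1B, chosen after its values were seen, had 0 counts in mock cells and was at least 52.4-fold higher after TNF against a floor of 3 counts over all mock sums. With IL1B at that bound the list's median stayed at 2.88. TNFAIP3, a deubiquitinase that shuts NF-kB off, rose by 2.61 ± 0.30, and the NF-kB subunit genes NFKB1 and NFKB2 by 1.44 ± 0.20 and 2.34 ± 0.27. The median was 2.90 in biorep1 and 2.77 in biorep2.

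Immediate early genes, which signalling turns on without new protein synthesis, went up more often than down: 12 of 29 were higher and 2 lower (15 and 2 adjusted over the list alone; 13 and 2 with a trended dispersion), with a median of 0.81 (adjusted p = 4.5e-09). It was 0.74 in biorep1 and 1.02 in biorep2. JUNB, an AP-1 subunit, rose by 2.39 ± 0.21, IER2 by 1.04 ± 0.11 and JUN by 0.81 ± 0.15. MYC, a growth-promoting transcription factor in the same list, fell by 1.29 ± 0.13, from 411 to 172 CPM, and was lower in 19 of 21 libraries (-1.52 in biorep1, -0.47 in biorep2). Of 24 components of TNF receptor signalling, 6 were higher and 0 lower (7 and 2 adjusted over the list alone; 3 and 0 with a trended dispersion; adjusted p of the list 0.141). REL, an NF-kB subunit, rose by 1.27 ± 0.11 and CFLAR, which blocks caspase 8, by 0.66 ± 0.14. CFLAR missed the threshold in the biorep1 libraries outside JD130 (0.54, adjusted p = 0.118), with sums per set of libraries (0.0623) and with limma on mean CPM per cell (0.0591). Of 20 apoptosis regulators, 2 were higher and 0 lower (2 and 2 adjusted over the list alone; 2 and 0 with a trended dispersion; list p = 0.487). The 2 were the survival factor MCL1 (0.73 ± 0.09) and CYCS, which encodes cytochrome c (0.40 ± 0.06). CYCS was 0.018 in biorep2 alone. It missed the threshold with sums per set of libraries (adjusted p = 0.179) and with limma on mean CPM per cell (0.0591). Of 23 interferon and antigen presentation genes, 2 were higher and 0 lower, also adjusted over the list alone (1 and 0 with a trended dispersion): B2M, the light chain of MHC class I (0.36 ± 0.03), and TAPBP, which loads peptides on it (0.43 ± 0.12; list p = 0.487). TAPBP missed the threshold with a trended dispersion (adjusted p = 0.058), without biorep1 batch 6 (0.0506), without biorep1 batch 12 (0.0513) and in either set of biorep1 libraries alone (0.0553 in JD130, 0.284 in the others). That list's median had the opposite sign to its test.

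Heat shock genes, which encode chaperones, moved up over all libraries: 15 of 18 were higher and 0 lower (16 and 0 adjusted over the list alone; 12 and 0 with a trended dispersion), with a median of 0.51 (adjusted p = 8.12e-23). The rise rested on biorep1, where the median was 0.65, against 0.0092 in biorep2. HSPA1A, whose counts cannot be separated from those of its copy HSPA1B, rose by 2.14 ± 0.25 (2.65 in biorep1, 0.039 in biorep2), DNAJA1 by 0.84 ± 0.09, HSP90AA1 by 0.46 ± 0.05 and HSP90AB1 by 0.21 ± 0.03. The 25 genes of the unfolded protein and ATF4 response split: 6 were higher and 16 lower (6 and 17 adjusted over the list alone; 6 and 12 with a trended dispersion), with a median of -0.69 (adjusted p = 4.23e-06). In biorep1 the median was -0.74 and in biorep2 0.19. Those that rose included the endoplasmic reticulum chaperones SDF2L1 (0.85 ± 0.08) and HSP90B1 (0.48 ± 0.05). Those that fell included PHGDH and ASNS, the asparagine synthetase gene, which went from 339 to 146 CPM (log2 change -1.37 ± 0.18; -1.80 in biorep1, 0.45 in biorep2).

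Of 13 p53 targets, 4 were higher and 0 lower (5 and 1 adjusted over the list alone; 3 and 0 with a trended dispersion; adjusted p = 0.00164), among them BTG2, PLK3, a stress-induced kinase (2.22 ± 0.31), and GADD45A, a growth arrest gene (0.50 ± 0.09). Of 18 glycolysis genes, 7 were higher and 0 lower (8 and 0 over the list alone; 7 and 0 with a trended dispersion; adjusted p = 4.23e-06), by smaller amounts: GAPDH by 0.38 ± 0.04, TPI1 by 0.33 ± 0.05, ENO1 by 0.23 ± 0.05 and LDHB by 0.17 ± 0.04. This list's rise, too, rested on biorep1: its median was 0.28 there and -0.05 in biorep2, where ENO1 was -0.04. Without the library as block, ENO1 and LDHB missed the threshold (0.164 and 0.176). Of 39 replication-dependent histone genes, 8 were higher and 1 lower (16 and 2 over the list alone; 3 and 0 with a trended dispersion; adjusted p = 4.14e-06), such as HIST1H2AH (2.08 ± 0.35) and HIST1H2AM (1.03 ± 0.21; adjusted p = 0.0539 with a trended dispersion and 0.165 in the JD130 libraries alone). Of 21 cholesterol synthesis genes, 2 were higher and 2 lower (3 and 2 over the list alone; 1 and 0 with a trended dispersion; list p = 0.629). The list's median had the opposite sign to its test.

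Erythroid and globin genes, which K562 cells express, changed in one direction only: 0 of 27 were higher and 7 lower, also adjusted over the list alone (5 with a trended dispersion), with an adjusted p of 0.0033 that rose to an adjusted p of 0.222 with an estimated correlation. The erythroid regulators LMO2 and NFE2 fell by 0.97 ± 0.15 and 0.91 ± 0.16 and HEMGN, a haematopoietic nuclear protein gene, by 0.59 ± 0.10. HEMGN did not pass in the JD130 libraries alone (-0.39, adjusted p = 0.0819) or in the series-wide matrix (-0.40, 0.106), nor NFE2 in that matrix (-0.58, 0.0538). GATA1, the main erythroid transcription factor, had 266 against 267 CPM, and the fetal globin gene HBG1, not separable from HBG2, 851 against 773 CPM (adjusted p = 0.312). The calls of the other 7 lists past the threshold (NF-kB, immediate early, heat shock, ATF4, p53, glycolysis, histones) held with an estimated correlation. Their adjusted p (camera) were much weaker with it: in that order 5.17e-08, 7.05e-04, 0.00187, 0.0267, 0.0267, 0.0278 and 0.0053.

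Markers of other blood and tissue cell types gave no call. None of 6 megakaryocyte markers (GP1BB -0.02 ± 0.14, GP6 0.21 ± 0.30; list p = 0.906), 5 monocyte and granulocyte markers (LYZ 0.03 ± 0.12, AIF1 0.19 ± 0.10; p = 0.629) or 3 lymphocyte markers (CD3D 0.45 ± 0.22; p = 0.79) passed, also adjusted over the list alone. EPCAM and KRT19, the 2 measured fibroblast and epithelial markers, had log2 values of -0.25 ± 0.09 (adjusted p = 0.0775; 1 lower over the list alone) and 0.06 ± 0.18.

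Most cell cycle and ribosomal genes did not pass the threshold, and those that did went both ways. Of 42 S phase genes, 4 were higher and 3 lower (5 and 3 over the list alone; 1 and 2 with a trended dispersion; list p = 0.629), with the ribonucleotide reductase subunit RRM2 up by 0.49 ± 0.09 and the DNA primase subunit PRIM1 down (-0.55 ± 0.10). Of 51 G2 and M phase genes, 3 were higher and 4 lower, also over the list alone (3 and 3 with a trended dispersion; list p = 0.79), with ANP32E up by 0.31 ± 0.06 (adjusted p = 0.0603 in the biorep1 libraries outside JD130) and the kinetochore gene NDC80 down (-0.43 ± 0.09). Of 83 ribosomal protein genes, 6 were higher and 3 lower, also over the list alone (4 and 3 with a trended dispersion; list p = 0.7), with RPL35 up by 0.19 ± 0.03 and RPL3 down (-0.19 ± 0.04). Both missed the threshold without the library as block. Its median, too, had the opposite sign to its test.

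**Figure D2:**
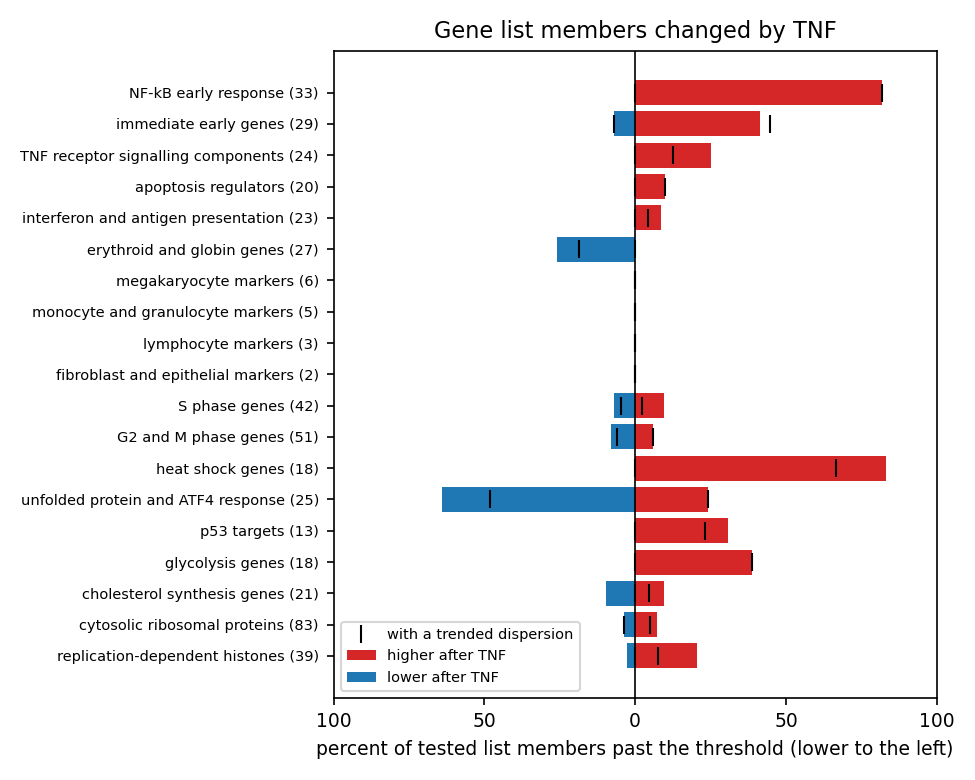
Percent of the tested members of each of 19 gene lists (number tested in brackets) that passed the threshold, as bars to the right for members higher and to the left for members lower after TNF; vertical ticks give the percent with a trended dispersion. In the NF-kB list 27 of 33 members were higher and in the heat shock list 15 of 18, while in the unfolded protein and ATF4 list 16 of 25 were lower.

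HSBP1, whose enhancer both guides were listed to target, had 197 ± 54.5 CPM in TNF and 179 ± 49.8 in mock cells, a log2 difference of 0.12 ± 0.09 that did not pass (adjusted p = 0.432; higher in 14 of 21 libraries). HSBP1 was chosen after its values were seen. Both treatments carried such a guide, so this comparison has no cells without one.

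In single cells, the response was seen in most treated cells. With every cell drawn down to 16100 counts, the NF-kB list took 0.353 ± 0.213% (SD over 488 cells) of a TNF cell's counts and 0.0581 ± 0.0765% of a mock cell's (579 cells). The mean difference over libraries was 0.298 ± 0.0624 percentage points (SD, n = 21; higher in 21 of 21; two-sided sign-flip permutation p = 1e-05, the smallest these can give). Within a library, the area under the ROC curve between TNF and mock cells averaged 0.937 ± 0.045. Of the TNF cells, 81.8% scored above the 95th percentile of all mock cells (0.149%). Against the mock cells of their own biorep, as planned, 82.7% did so in biorep1 and 53.7% in biorep2. The percentile of the mock cells was higher in biorep2 (0.297% against 0.137%).

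**Figure D3:**
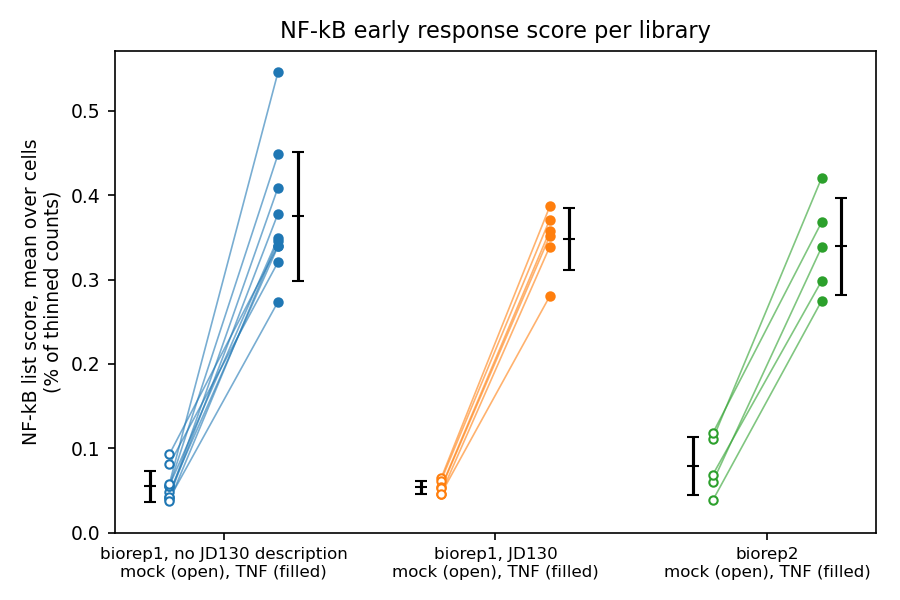
Mean NF-kB list score (percent of a cell's thinned counts, vertical axis) of mock cells (open points) and TNF cells (filled points) in each of the 21 libraries, joined by a line per library and grouped as 10 biorep1 libraries without the JD130 description, 6 with it and 5 of biorep2, with the mean and SD over libraries as black bars. In all 21 libraries the TNF cells lie above the mock cells, by 0.298 percentage points on average.

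A count of NFKBIA was seen in 92.3 ± 6.33% of TNF and 36.8 ± 10.6% of mock cells (SD, n = 21 libraries), and of ICAM1 in 81.9 ± 11.6% and 18.3 ± 8.59%. The transcripts with the sparsest mock signal were BIRC3, seen in 21.5% of TNF and 1.08% of mock cells, CXCL8 (17.4% and 1.00%) and TNFAIP3 (27.6% and 4.34%). IER2 (75.2% and 46.0%), JUN (49.6% and 34.8%), NFKB1 (35.0% and 14.6%) and NFKB2 (15.8% and 4.46%) were also seen in more TNF cells. Adjusted p ranged from 2.17e-05 to 1.73e-04 for these 9 genes. Of the genes not chosen for TNF, ACTB was seen in 100% of both, GAPDH in 98.0% and 99.4% and HBG1 in 98.0% and 97.9%, shares that can hardly rise. In the summed counts ACTB rose by a log2 of 0.23 ± 0.05 (adjusted p = 0.00274), as did GAPDH by 0.38. ACTB missed the threshold without the library as block (0.0543) and with limma on mean CPM per cell (0.263), and was -0.0015 in biorep2 alone. With sums per set of libraries, ACTB and GAPDH both missed it (0.224 and 0.0802). GATA1 was seen in 78.3% and 73.7% (adjusted p = 0.294; without thinning 79.0% and 68.9%, adjusted p = 5.07e-04). Free RNA from lysed cells can give counts in cells that do not express a gene, and all cells here are of one line, so no cell type that lacks these genes sets a background. With 5 libraries, biorep2 alone could not go below an exact p of 0.0625.

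TNF cells carried more counts than mock cells: the medians per library differed by a log2 of 0.87 ± 0.80 (SD, n = 21; 19 of 21 higher; permutation p = 2e-05). This held in the biorep1 libraries outside JD130 (0.92 ± 0.44, permutation p = 0.00204, 10 of 10 higher), while the 6 JD130 libraries gave 0.16 ± 0.23 (exact permutation p = 0.188) and the 5 of biorep2 gave 1.64 ± 1.11 (exact permutation p = 0.125). TNF cells also had more genes detected (by 1132 ± 1205; p = 5e-05), by 1085 ± 739 in the biorep1 libraries outside JD130, 83.3 ± 243 in JD130 (exact permutation p = 0.406) and 2485 ± 1420 in biorep2 (exact permutation p = 0.0625). The share of ribosomal protein counts was lower by the same test (-0.447 ± 0.666 percentage points; lower in 18 of 21; p = 0.00438), with -0.619 ± 0.773, -0.499 ± 0.312 and -0.0387 ± 0.681 points in these 3 sets.

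The same contrast was run in both bioreps, and the test of the difference asked where they part. DDIT4, a stress-induced inhibitor of mTOR, was lower after TNF in biorep1 (log2 -2.40) and higher in biorep2 (1.31), a difference of 3.68 ± 0.35 (adjusted p = 9.95e-08). ASNS (-1.80 and 0.45; difference 2.24 ± 0.26, adjusted p = 5.51e-06), MTHFD2, a mitochondrial folate enzyme (-0.80 and 0.35; 1.12 ± 0.15, 1.14e-04), and ANXA1, a phospholipid-binding protein (-0.71 and 0.55; 1.25 ± 0.18, 1.70e-04), also differed. Fitted alone, biorep1 called all 4, while biorep2 called none of them (adjusted p of 0.283 to 0.763), and in biorep2 the CPM difference of ASNS, without normalization factors, was 306 in batch 5 and -22.3 to 35.2 in the other 4 libraries. ZNF324, a zinc finger gene, was listed at 0 in the 5 mock sums of biorep2 and had 101 counts in their TNF sums, at least 35.7-fold higher against a floor of 3 counts over the mock sums; its log2 change in biorep1 was -1.03.

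In all, the effect differed between bioreps for 216 of 12150 genes (112 more positive in biorep2, 104 more negative). It did so for 174 with a trended dispersion and for 666 of 10736 with a DESeq2 Wald test. On simulated data with 11960 genes tested, 35.4% of the calls of the planned edgeR test were false, and 9.18% of differences of a log2 of 1 were recovered. By list, heat shock genes had the lowest p for a difference: their median was 0.65 in biorep1 and 0.0092 in biorep2 (adjusted p = 1.21e-04 with an estimated correlation). Glycolysis genes followed (0.28 and -0.05; 8.90e-04), as did the ATF4 list (-0.74 and 0.19; 0.0019). The bioreps also differed in cell quality: 65.4% of mock and 40.3% of TNF cells had under 2000 genes in biorep2, against 17.6% and 7.82% in biorep1. The p53 targets (0.28 and 0.67; 0.0779) and the NF-kB list (0.887) did not pass this test. Fitted alone, biorep2 gave 15 changed genes and biorep1 1984; with 9181 genes simulated for biorep2, 11.8% of changes of a log2 of 1 were recovered.

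Within biorep1, the 6 JD130 libraries and the 10 others were compared in the same way. No gene passed: 0 of 11885 with edgeR, with DESeq2 and with a trended dispersion, where 650, 460 and 281 genes had an unadjusted p under 0.05. On simulated data with 11730 genes tested, the edgeR test recovered 50% of differences of a log2 of 2 and 21.6% of those of 1; smaller sizes were not simulated. The ATF4 members that were lower had a median log2 change of -1.42 in JD130 and -1.49 in the other libraries, and the heat shock members that were higher 0.54 and 0.80.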

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

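The tests that compare the medians of JD130 with those of the other biorep1 libraries, those of a difference between cultures, those without each biorep2 library, and the limits of 2000 genes per cell and of sgRNA reads were chosen only after the data were seen; the others in this part were planned.

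Genes of the ATF4 response that were lower after TNF over all libraries, such as ASNS and DDIT4, were so in biorep1 more than in biorep2. The median log2 change of these 16 members was -1.51 in biorep1 and 0.45 in biorep2 (15 members measured). The middle member in biorep2 was ASNS, which stood apart in batch 5, and without batch 5 the biorep2 median was 0.11. These members were picked by a fit in which 16 of 21 libraries were of biorep1, which favours a larger fall there. Over all 25 tested members the medians were -0.74 in biorep1 and 0.19 in biorep2. That whole list differed between bioreps at an adjusted p of 0.0019 (camera with an estimated correlation). A difference in counts per cell is argued against. In the JD130 libraries, where both treatments had similar depth, the median of the 16 members was 0.954 times that in the other biorep1 libraries. Over all libraries, the median with cells of 2000 or more genes was 0.978 times that with all cells. This ratio could hardly move, since 7.82% of TNF and 17.6% of mock cells in biorep1 had fewer genes, so it decides nothing. By biorep, the medians with cells of 2000 or more genes were -1.52 in biorep1 and 0.53 in biorep2. The whole list still differed (camera with an estimated correlation, adjusted p 0.00327). Shallow barcodes, more frequent in biorep2, are thus argued against as the source of the difference between bioreps. A difference between the TNF and mock cultures of biorep1 other than TNF may account for the fall there. It stays open, because the labels give no separate cultures. For the picked members the difference between the bioreps was 1.96, and 1.62 without biorep2 batch 5. A difference between bioreps in the response itself stays open as well and was not tested.

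Heat shock genes that were higher after TNF, such as HSPA1A and DNAJA1, rose more in biorep1. The median of these 15 members was 0.73 there and 0.02 in biorep2 (-0.0051 to 0.027 without each biorep2 library). They were picked by the same fit, which favours a larger rise in biorep1. Over the whole list of 18 the medians were 0.65 in biorep1 and 0.0092 in biorep2. That list differed between bioreps with an adjusted p of 1.21e-04 (camera with an estimated correlation). Over all libraries, the median with cells of 2000 or more genes was 1.10 times that with all cells, a ratio that could hardly move here either. By biorep, the medians of the 15 members with such cells were 0.76 in biorep1 and 0.029 in biorep2. The whole list still differed (camera with an estimated correlation, adjusted p 6.29e-04). Shallow barcodes are thus argued against as the source of the difference between bioreps. The difference in counts per cell could have a part and stays open, as the median in the JD130 libraries was 0.669 times that in the others, between the bounds set for either answer. Handling of the biorep1 cultures other than TNF could also account for the rise (difference of -0.71 between the bioreps for the picked members). It cannot be told apart from the treatment, because the labels give no separate cultures. A biological difference between bioreps stays open and was not tested.

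Among mock cells, some had an NF-kB list score above the median TNF cell of their biorep, and the tests here ask whether barcode assignment or free RNA may lie behind them. Of 31 mock cells with 1 sgRNA read, 6 did so, and of 357 with 10 or more reads, 0, which allows a share of up to 0.840%: a difference of 19.4 percentage points (95% interval 9.13 to 36.3). A wrong treatment where 1 read was seen is a candidate explanation that this goes with. Of 203 mock cells under 2000 genes 11.8% did so, against 1.49% of 604 others without thinning. This is a difference of 10.3 percentage points (6.36 to 15.5) and goes with RNA from other cells in shallow barcodes. An unthinned score also varies more in cells with few counts, so this test cannot tell such RNA from sampling. Both differences held beside the other. Among cells of 2000 or more genes, the difference by sgRNA reads was 17.6 points (3 of 17 cells against 0 of 347). Among cells with 2 or more reads, the difference by genes detected was 10.4 points. Cells were pooled over libraries, so the intervals do not measure the spread between libraries. Nor were the bioreps held apart: 24.4% of mock cells in biorep2 had 1 read and 65.4% under 2000 genes, against 7.79% and 17.6% in biorep1. No biological explanation was tested.

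Other values differed between bioreps by the test of the difference. The effect differed for 216 genes. Of 60 regroupings of the libraries, 1, the real one, gave as many, and the highest of the others gave 63. Chance in how the libraries were grouped is thus argued against, as far as 60 regroupings can tell. A difference between cultures that libraries of a biorep may share is not argued against. The single genes with the lowest p were DDIT4 (a log2 difference of 3.68), ASNS (2.24), MTHFD2 (1.12), ANXA1 (1.25) and ZNF324 (9.14, a fitted value that depends on the prior count, since its mock sums in biorep2 hold 0 counts). Glycolysis genes differed as a list with an adjusted p of 8.90e-04. For the number of genes changed by TNF, 100 sets of treatment labels swapped within libraries were compared. Of these, 1, the real one with 1318 genes, gave as many, and the highest other gave 71. Chance in the labels of the libraries is thus argued against. A swap turns a real effect into spread between libraries, however, which can lower the other counts. A difference between cultures or between the 2 guides is not argued against. For the difference between JD130 and the other biorep1 libraries, the count of regroupings cannot say whether chance is excluded: with 0 genes in the real grouping, any regrouping gives as many (60 of 60; the highest other gave 8).

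In biorep2, a single library stood far from the other 4 in the CPM difference, TNF minus mock (here without normalization factors), for 12 of 114 values tested. Chance would put about 1 in 20 so far out if values were independent and normally distributed. These come from few cells and from the same libraries, so their own chance rate is not known and 12 is not shown to be an excess. In batch 2, CXCL8 stood at 441 (others at most 48.7), LTB at 299 (94.1), BTG2 at 388 (89.8) and SDC4 at 242 (63.4). In batch 5, ASNS stood at 306 (others at most 35.2), HIST1H4A at 33.3 (7.30), MYC at -544 (others at least -88.7), NUDT16P1 at -55.6 (-10.7) and CCND1 at 5.13 (others at least 34.8). C10orf10 stood at 45.5 in batch 4 (others at most 10.2), RPL13A at 474 in batch 3 (others at most -5.99) and HSBP1 at -114 in batch 1 (others at least 67.8).

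Barcodes outside the comparison carried a signal too. Of 91 barcodes with no treatment barcode that reached 16100 counts, 73.6% scored above the 95th percentile of mock cells on the NF-kB list, and of 189 with both, 57.1%. The guide vector stood at 2672 CPM in mock cells, 1426 in TNF cells, 1913 in barcodes with both and 337 in those with neither.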

How the results depend on the processing

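The trended dispersion, limma voom for single genes, robust fit, JD130 libraries alone, other biorep1 libraries alone, cells with 2 or more sgRNA reads, cells with 2000 or more genes and sums over transcripts were chosen only after the data were seen. Of 106 named genes, 95 passed the threshold. Their 4248 values under the alternatives had the same direction and passed in 3863 cases, missed the threshold in 375 and reversed in 10, all 10 in biorep2 alone. Many alternatives reuse nearly the same data, such as each library left out in turn, so much of this agreement is built in. Of the 95, 71 missed the threshold with sums per biorep and 53 with sums per set of libraries, the units that fit a shared culture. In biorep2 alone 73 kept their direction but missed it, and 14 missed it with a trended dispersion. The planned minimum of 1000 counts per cell changed nothing, as it removed no cell. On simulated data with 680 changed of 11948 genes, 22.8% of the calls of the planned edgeR test were false, against 3.15% with the trended dispersion. Why biorep2 alone called few genes was not tested; with 9181 genes simulated for it, 11.8% of changes of a log2 of 1 were recovered, and with 5 libraries the exact p of a share could not go below 0.0625. For values given here without a stated reason, the cause was not tested.

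Without each library in turn, the number of changed genes ranged from 1072 to 1443. Without each of the 5 biorep2 libraries, the genes that differ between bioreps ranged from 173 to 288; no biorep1 library was left out there. Reversals there concern genes that did not pass: GP1BB ranged from -0.19 to 0.077, LYZ from -0.019 to 0.079, KRT19 from -0.10 to 0.14, GATA1 from -0.073 to 0.050 and ZNF324 from -0.31 to 0.21. All gene values here are log2 changes.

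The count of changed genes, against 1318 (729 higher, 589 lower), moved as follows. With the trended dispersion it was 682 (455, 227), with ZNF324 at -0.26. Without the library as block it was 768 (385, 383), with ZNF324 at -0.015. Sums per biorep gave 36 (30, 6), with LYZ at -0.017 and KRT19 at -0.078, and sums per set of libraries 84 (61, 23), with KRT19 at -0.023; both have far fewer sums. Limma on mean CPM per cell gave 265 (163, 102), with LYZ at -0.32, ZNF324 at -0.13 and HSBP1 at -0.0078. Biorep1 alone gave 1984 (983 lower), with ZNF324 at -1.03 and an adjusted p of 0.906 for the G2 and M list, whose direction turned. The biorep1 libraries outside JD130 gave 854 (457 higher), with GP6 at -0.051 and ZNF324 at -1.25.

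Biorep2 alone gave 15 (13, 2). There ASNS was 0.45, DDIT4 1.31, MTHFD2 0.35, ANXA1 0.55, USP1 -0.24, TUBB4B -0.42, ENO1 -0.043, RPL13A 0.046, HIST3H2A 0.50, ACTB -0.0015, LYZ -0.17 and KRT19 -0.48. In biorep2, 5 lists passed against 8. The S phase (adjusted p = 0.375), heat shock (0.517), glycolysis (0.318), ATF4 (0.00367) and ribosomal protein (9.29e-13) lists had the other direction, with a preset correlation; the difference of the ribosomal protein list between bioreps had an adjusted p of 0.742 with an estimated one. The median counts per cell differed by 1.64 and the NF-kB score by 0.260 percentage points, neither of which 5 libraries can take past the threshold, and 0 of 9 genes passed for the share of cells. JD130 libraries alone gave KRT19 -0.30, GATA1 0.13 and ZNF324 -0.65. There the megakaryocyte (adjusted p = 0.815), lymphocyte (0.766), G2 and M (0.766) and ribosomal protein (0.214) lists turned, counts per cell differed by 0.16, and the shares of cells with HBG1 and GATA1 differed by -0.555 and -1.85 points. With all biorep2 cells together, the HBG1 share differed by -0.337 points. Without thinning, the GAPDH share differed by 0.0739 points, and GATA1 passed (10.1 points, higher in 17 of 21 libraries, adjusted p = 5.07e-04), in TNF cells that were deeper.

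With a DESeq2 Wald test, 666 genes differed between bioreps, against 216, and KRT19 was -0.00099 and ZNF324 -0.30. With DESeq2 factors, ZNF324 was -0.011. With no factors, LYZ was -0.022 and ZNF324 -0.036, and the megakaryocyte list turned (adjusted p = 0.965). With no filter, ZNF324 was -0.0055. The series-wide matrix gave GP1BB 0.077, EPCAM 0.017, KRT19 -0.37, GATA1 0.16 and ZNF324 -0.63. Without the top 5% of cells, where 19 libraries stayed, GP1BB was 0.070, KRT19 -0.13 and ZNF324 -0.59. With 2 or more sgRNA reads (20 libraries), ZNF324 was -0.20, and with sums over transcripts, -0.0050. Without ribosomal protein genes, ZNF324 was -0.0064. With cells of 2000 or more genes, the ribosomal protein list turned (adjusted p = 0.956).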

Other observations

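All genes in this paragraph and the next were chosen only after their values were seen, as the 8 rises and 8 falls with the lowest p outside the fixed lists that passed with both dispersions; 366 higher and 184 lower genes met that description. CD69, an early activation antigen of lymphocytes, rose from 58.5 to 361 CPM (log2 change 2.63 ± 0.14; higher in 21 of 21 libraries). SQSTM1, the autophagy receptor p62, rose from 78.7 to 266 CPM (1.76 ± 0.10; 21 of 21), and FTL, the ferritin light chain, from 5926 to 7449 CPM (0.33 ± 0.03; 20 of 21). EFNA1, an ephrin ligand, rose by 2.74 ± 0.26, and the kinase gene PIM3 by 1.62 ± 0.16. CCND1, which encodes cyclin D1, rose by 1.64 ± 0.19 and MXD1, a dimerization partner of MAX that opposes MYC, by 1.60 ± 0.19, beside the fall of MYC. The small non-coding RNA gene SNAR-E rose by 1.93 ± 0.26 (0.64 in biorep2 alone). It missed the threshold with sums per set of libraries (adjusted p = 0.129).

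CITED2, a transcriptional coregulator, fell from 125 to 49.0 CPM and was lower in 21 of 21 libraries (log2 change -1.32 ± 0.14). HHEX, a haematopoietic homeobox gene, fell by 0.84 ± 0.11, MS4A3, a gene of myeloid cells, by 0.81 ± 0.09, and SAMSN1, a signalling adaptor of blood cells, by 0.69 ± 0.08. PCK2, the mitochondrial phosphoenolpyruvate carboxykinase, fell by 1.28 ± 0.18, and EPRS, a tRNA synthetase, by 0.37 ± 0.05. ZBTB34 and CNTRL, a centrosome gene, fell by 1.63 ± 0.23 and 0.87 ± 0.11. In biorep2 alone the falls of PCK2, EPRS and SAMSN1 were small (-0.23, -0.15 and -0.19). Those of CITED2, MS4A3, HHEX and CNTRL were -1.63, -0.86, -0.62 and -0.71 there. PCK2, EPRS and HHEX missed the threshold with limma on mean CPM per cell (adjusted p of 0.176, 0.104 and 0.0818). With sums per set of libraries, EPRS and CNTRL missed it (0.168 and 0.0566).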
